A study of Mus musculus with 16 samples.

How the data were processed

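The series holds bulk RNA sequencing of double-positive (DP) thymocytes sorted by flow cytometry from mice. Per the labels, total RNA was taken with Trizol and a column kit, and libraries were made by BGI's own protocol. The labels place 16 libraries in 5 groups: young WT (3), old WT (4), young METTL3 KO (3), and WT (3) and METTL3 KO (3) with no age stated. Per the submitters' processing notes, reads were aligned with HISAT2 2.0.5 to mm10. The program that counted reads, its annotation and its strand setting are not given in the sources used here. The deposited files hold 1 raw read count per gene and library, and end in 5 summary lines (reads outside genes, ambiguous, of low quality, not aligned and not uniquely aligned), as the authors deposited them.

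Files of the 10 libraries with an age list 55335 gene identifiers, of which 55154 matched the mouse gene table used for symbols, and the other 6 files list 54532, of which 54409 matched, with 54113 in both. Coordinates and gene features came from the GENCODE annotation of mm10. Gene counts made up 41.6% to 43.2% of all counted entries in libraries with an age, and 47.5% to 51.2% were counted as outside genes. The latter may include reads opposite a gene's strand. Single-exon genes opposite an expressed gene had a median density of 0.979 of that gene in these libraries. In the set without an age, 50.5% to 52.2% of entries were not aligned, against 0.58% to 0.83% in the other libraries, so the sets were compared only through the difference between KO-labelled and WT libraries within each. The labels state no batch, sex or litter. Sex was read from Xist and Y-linked genes as 1 female and 2 male in young WT, 2 and 2 in old WT, 1 and 2 in young KO, 0 and 3 in WT without an age and 2 and 1 in KO without an age. Intervals cover the spread between libraries or counting error only, except that of the X chromosome ratio, which comes from resampled genes.

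Counts were tested with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1): genes were kept by filterByExpr, scaled by TMM and fitted by a robust quasi-likelihood model, with Benjamini-Hochberg adjustment and a threshold of 0.05, two-sided. The age and young KO comparisons came from 1 fit of the 10 libraries with an age, which share an estimate of spread. The KO comparison without an age used its 6 libraries, and an interaction of genotype and set over 12 libraries tested whether these differences are unequal. A total of 40 gene lists (845 distinct symbols, 99.3% of them in the gene table) were tested by camera with a preset correlation between genes of 0.01, where at least 3 members were tested, with adjustment over the lists of 1 comparison. Camera with an estimated correlation and fry were alternatives. Counts "adjusted over the list alone" apply Benjamini-Hochberg to a list's own genes. A called list's mean log2 CPM was also compared between groups with each library left out, a comparison added after the data were seen. Groups, comparisons, lists, the rule for named genes and the alternatives were fixed before the data were examined, except where a later choice is named as such.

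The text names 13 fixed genes (Mettl3, Gpx4, Slc7a11, Acsl4, Tfrc, Ptgs2, Fth1, Ncoa4, Igf2bp2, Cd4, Cd8a, Rag1 and Cdkn1a). It also names the 6 largest rises and 6 largest falls among called genes of at least 5 CPM whose groups do not overlap and that have an ordinary gene symbol, and up to 4 members with the smallest p of each list described. Other genes named are partners on the other strand or were chosen after their values were seen, as were Cst3 and Plag1. A few genes that the rule names are not reported here.

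Alternatives were DESeq2 size factors, library size alone, no filter on low counts, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, a fit of the groups compared alone, a fold threshold, and each library left out. Sex as a covariate, an offset for GC content and transcript length, and genes of at least 5 CPM in WT were added after the data were seen. The procedure was tested on simulated data in which 200 genes of at least 5 CPM were changed. At 2-fold, 86.6% of changes were recovered for age, 91% for young KO, 61.2% for KO without an age and 50.7% for the interaction. At 1.5-fold, 50.7%, 40.3%, 9% and 6% were recovered in the same order. Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 prepared tables and figures. No library was left out of the main comparisons. Alternative splicing and m6A itself were not analysed here, since the files hold gene counts.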

Results

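RNA from sorted mouse thymic double-positive cells (DP, the CD4 and CD8 expressing stage at which T cell receptors are selected) was sequenced in 16 libraries. METTL3 is the catalytic subunit of the complex that writes N6-methyladenosine (m6A) on RNA. The labels gave an age and a genotype for 10 libraries, which were 3 young WT, 4 old WT and 3 young METTL3 KO. A further 3 WT and 3 METTL3 KO libraries had a genotype and no age. Gene counts summed to between 9781368 and 10307780 in each library with an age, 15927134 and 16167074 in the WT libraries without one, and 10575795 and 13740694 in their KO counterparts. Nothing in the labels says that the replicates came from separate animals, so adjusted p-values measure the spread between these samples. Gene levels are given as CPM (counts scaled by TMM per library total, mean ± SD), and differences as log2 fold changes ± SE.

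Mettl3 was read first, as a check of the labels. The gene (ENSMUSG00000022160) lies on chromosome 14 at 52294841 to 52305128 of mm10. It had 678, 656 and 591 counts in the young WT libraries and 626, 653 and 647 in the libraries labelled young KO, or 63.8 ± 3.66 against 63.7 ± 1.33 CPM (n = 3 each). The log2 difference was 0.00 ± 0.08 (adjusted p = 1). The libraries labelled young KO therefore showed no loss of Mettl3 at gene level, with a 95% interval of -0.20 to 0.20. Old WT libraries had 675, 611, 599 and 620 counts (62.7 ± 2.94 CPM, n = 4). In the libraries without an age, Mettl3 fell from 48.9 ± 4.96 CPM in WT (835, 742 and 692 counts) to 32.7 ± 5.82 CPM in KO (394, 441 and 357 counts), a log2 change of -0.58 ± 0.18 (adjusted p = 0.0189, lower in 3 of 3). That call was lost with scaling by library size alone (-0.48, adjusted p = 0.0653) and without WT replicate 1 (-0.55, adjusted p = 0.0695). Over all 16432 genes of this comparison the lower quartile of the log2 change was -0.61. A fall of this size was therefore common and says little about the label. The labels do not say which part of the gene was deleted, and Mettl3 shares 680 bp with Tox4 on the other strand, so the gene count is a partial check. Tox4 was the more abundant of this pair in young WT. Genes appeared to take reads from the opposite strand in libraries with an age and not in the others. Mettl3 counts in the libraries with an age may therefore hold Tox4 reads.

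**Figure D1:**
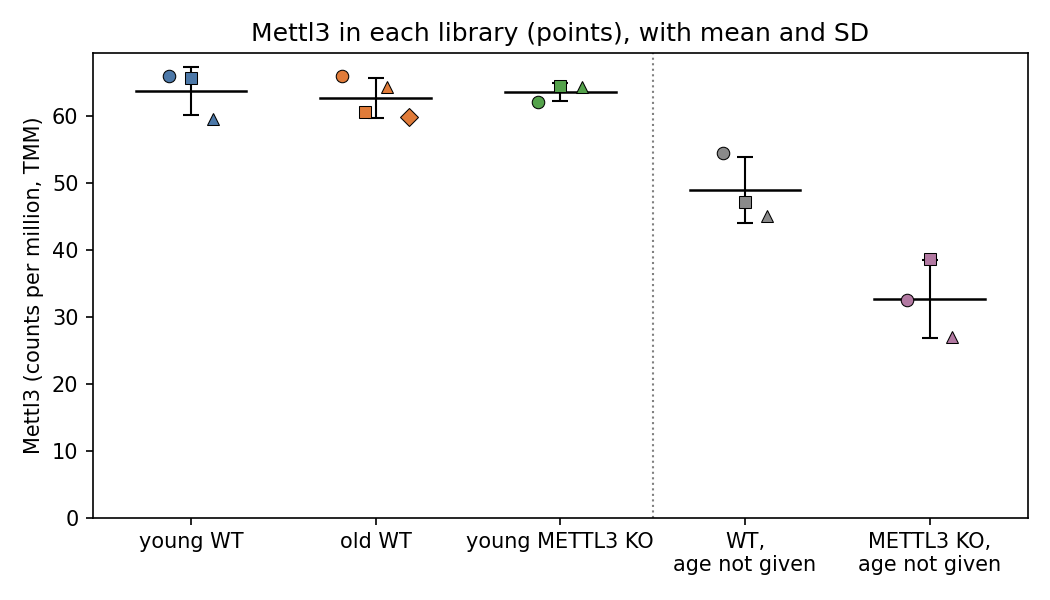
Mettl3 in CPM in each of the 16 libraries, by group, with the group mean (long line) and SD (bars). The young libraries labelled KO averaged 63.7 CPM beside 63.8 in young WT, and the KO libraries without an age averaged 32.7 beside 48.9 in their WT.

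The comparison of old with young WT asks what ageing changes in DP cells. The call with the smallest adjusted p was Igf2bp3, an RNA-binding protein of the fetal programme and an m6A reader, which fell from 32.9 ± 5.55 CPM in young WT (n = 3) to 3.70 ± 0.907 in old WT (n = 4), a log2 change of -3.14 ± 0.18 (8.83-fold lower, adjusted p = 4.15e-06). Bmpr1a, a receptor for bone morphogenetic proteins, rose from 0.567 ± 0.385 to 11.8 ± 1.91 CPM (20.6-fold, log2 change 4.36 ± 0.36, adjusted p = 0.000128). Fzd10, a Wnt receptor, fell 23.8-fold from 12.8 ± 6.92 to 0.522 ± 0.254 CPM (log2 change -4.57 ± 0.49, adjusted p = 0.00199). Fgf13, an intracellular member of the fibroblast growth factor family, fell from 42.6 ± 1.99 to 16.7 ± 3.03 CPM (-1.35 ± 0.13, adjusted p = 0.000438), and Rtkn fell from 9.45 ± 1.49 to 2.26 ± 0.704 CPM (-2.06 ± 0.24, adjusted p = 0.00199). On mm10, Igf2bp3 (ENSMUSG00000029814) lies on chromosome 6 at 49085223 to 49214957 and Bmpr1a on chromosome 14 at 34410734 to 34503341. Each of these 5 genes kept its call when any 1 library was left out, with log2 changes of Bmpr1a between 4.05 and 5.05.

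Among the other large rises were Cttn, which binds cortical actin (1.61 ± 0.21), Gpc1, a cell-surface heparan sulfate proteoglycan (1.5 ± 0.21), Aldh1l1 of folate metabolism (1.36 ± 0.23), Aim2, a sensor of cytosolic DNA (0.95 ± 0.15), and Apol7e (0.89 ± 0.15). Wscd1 (-2.07 ± 0.31) and Hspg2, which encodes perlecan (-1.61 ± 0.26), fell. The adjusted p of these 7 genes lay between 0.0056 and 0.0257. All 7 calls were lost without young WT replicate 1 (0.0593 to 0.128), all 7 without replicate 3 (0.0701 to 0.197), and those of Aldh1l1, Aim2, Apol7e, Wscd1 and Hspg2 without replicate 2 (0.109 to 0.232). Those of Aldh1l1 (0.0558), Apol7e (0.0502) and Hspg2 (0.0668) were lost without old WT replicate 1, and that of Hspg2 without old WT replicate 2 (0.0677). Igf2bp3, Rtkn, Gpc1, Bmpr1a, Aldh1l1 and Apol7e overlap a gene on the other strand. Igf2bp3 shares 1529 bp with Malsu1 (-1.09 ± 0.19, adjusted p = 0.0309) and Rtkn 694 bp with Wdr54 (-2.42 ± 0.24, adjusted p = 0.000487), so the split of reads within these pairs is uncertain.

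A total of 36 of 14228 genes passed in edgeR, 18 higher and 18 lower in old WT, and 1716 had an unadjusted p under 0.05. The count was 13 without young WT replicate 1, 10 without replicate 2 and 8 without replicate 3, and 59 without old WT replicate 4. The balance differed too: without young WT replicate 1, 3 were higher and 10 lower. DESeq2 called 153 genes (109 higher and 44 lower), all 36 among them, and a fit of the old and young WT groups alone called 11.

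**Figure D2:**
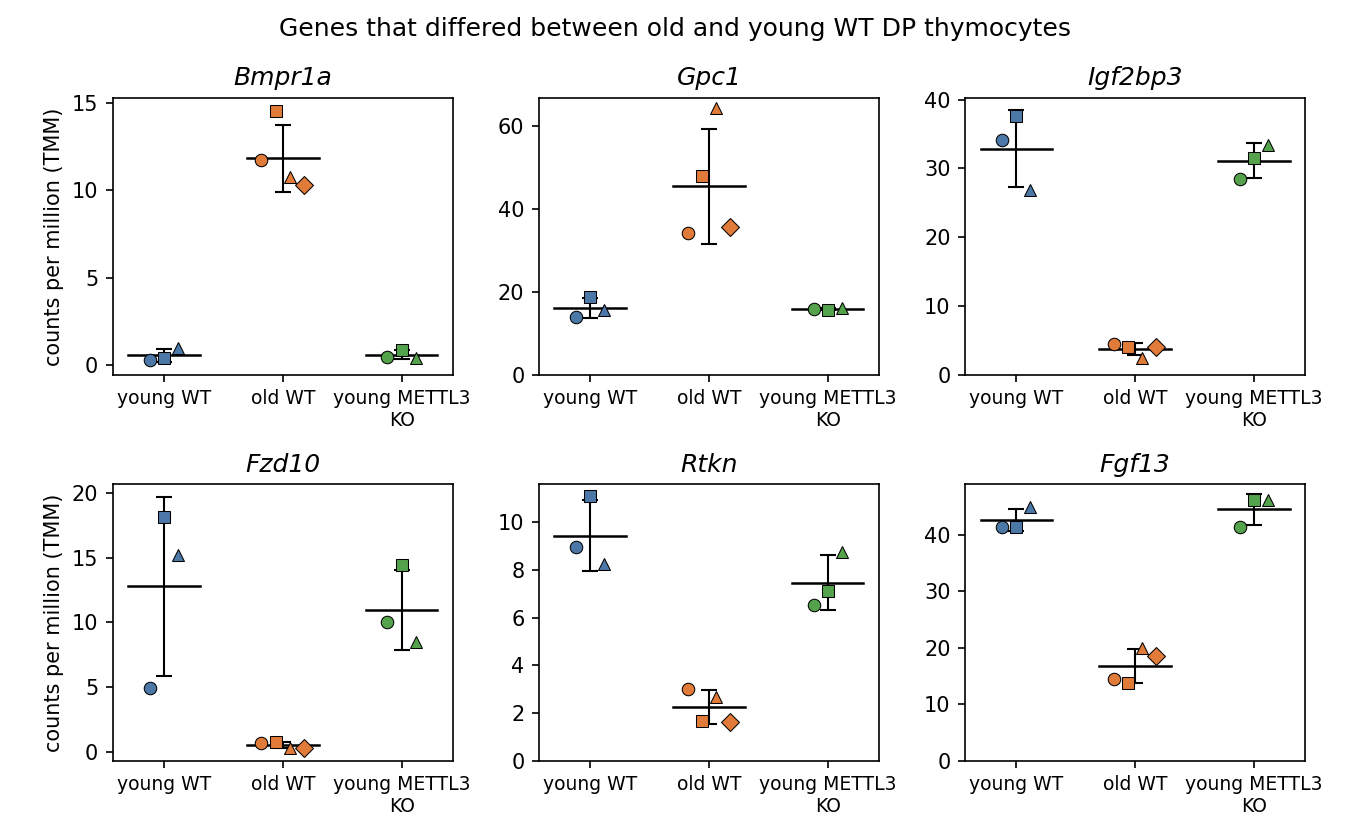
CPM of 6 genes in the libraries with an age, with each library as a point and the group mean and SD as lines. Old WT libraries lie apart from young WT in each panel, and the young libraries labelled KO are shown for reference.

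Several gene groups moved together with age through small changes per gene. Genes raised on positive selection, the step at which DP cells with a useful receptor are kept, rose as a group: 22 of 23 were above 0 with a median log2 change of 0.50 (camera adjusted p = 1.56e-07; adjusted p = 0.402 with an estimated correlation). No member passed, over all genes or adjusted over the list alone. Cd5 (0.29 ± 0.09), which tracks receptor signal strength, Gata3 (0.32 ± 0.10), Ccr4 (0.54 ± 0.18) and Egr1 (0.69 ± 0.23) had the smallest p. Interferon-stimulated genes also rose as a group, with 31 of 33 above 0 and a median of 0.56 (camera adjusted p = 7.21e-11; adjusted p = 0.434 with an estimated correlation). No interferon-stimulated gene passed over all genes in edgeR and 8 were higher adjusted over the list alone, with Gbp2 (0.70 ± 0.14), Ddx58 (0.55 ± 0.13), Parp14 (0.65 ± 0.17) and Ifih1 (0.56 ± 0.15) first by p. Of these, DESeq2 called Gbp2 (0.00323), Ddx58 (0.0261) and Parp14 (0.0405), and edgeR called Gbp2 with the replicate number as a block (0.0271) and without old WT replicate 4 (0.0156). The block in effect also leaves that library out, since no other group has a replicate of that number. Much of both rises lay in old WT replicate 3. The difference in mean log2 CPM between old and young WT was 0.43 for positive selection genes and 0.21 without that library, and 0.45 and 0.22 for interferon-stimulated genes, whose mean in old WT replicate 4 (2.91) was below each young WT library (3.02 to 3.20). No list call in this comparison, or in either KO comparison, held with an estimated correlation.

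Replication-dependent histone genes fell as a group in old WT, with a median of -0.90 and 2 of 33 above 0 (camera adjusted p = 4.07e-18, or 0.402 with an estimated correlation). This list was set as one of quality, since its mRNAs mostly lack poly(A). How far library preparation bears on its counts was not tested. None passed over all genes in edgeR and 6 were lower adjusted over the list alone, among them Hist1h1b (-1.64 ± 0.37) and Hist1h1a (-1.79 ± 0.50). DESeq2 called both (0.012 and 0.0353), and edgeR called Hist1h1a without old WT replicate 1 (0.0467). DNA replication genes (median -0.18, 0 of 26 called, camera adjusted p = 0.000158; adjusted p = 0.589 with an estimated correlation) and mitosis genes (median -0.10, 0 of 26 called, camera adjusted p = 0.0197; adjusted p = 0.774 with an estimated correlation) fell as groups. The replication call was lost without old WT replicate 4 (adjusted p = 0.114) and with the replicate number as a block (0.149). The mitosis call was lost without young WT replicate 1 (0.205) and turned upward without old WT replicate 4 (0.208) and with the block (0.221). Cytosolic ribosomal protein genes fell slightly (median -0.18, 7 of 78 above 0, camera adjusted p = 3.35e-08; adjusted p = 0.597 with an estimated correlation), as did nuclear oxidative phosphorylation genes (median -0.16, 6 of 41 above 0, camera adjusted p = 5.51e-05; adjusted p = 0.589 with an estimated correlation). None of their members passed, over all genes or adjusted over the list alone. The oxidative phosphorylation list lost its call with the replicate number as a block (0.0885). Several of these differences in mean log2 CPM moved by over 1.5 times with 1 library left out. Without old WT replicate 4, histone genes went from -0.94 to -0.62, replication genes from -0.19 to -0.08, mitosis genes from -0.15 to 0.06, ribosomal protein genes from -0.17 to -0.07 and oxidative phosphorylation genes from -0.14 to -0.07. Mitosis genes stood at -0.23 without old WT replicate 2 and -0.24 without replicate 3. Ribosomal protein and oxidative phosphorylation genes stood at -0.27 and -0.22 without old WT replicate 1, and at -0.08 and -0.09 without young WT replicate 3.

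Glycolysis genes rose as a group (median 0.18, 15 of 19 above 0, camera adjusted p = 0.00441; adjusted p = 0.434 with an estimated correlation). Pdk1, a kinase that restrains pyruvate dehydrogenase, was the only member called, over all genes and adjusted over the list alone (0.47 ± 0.09, adjusted p = 0.0454). The Pdk1 call was lost without any of the 3 young WT replicates (0.162, 0.37 and 0.282) and without old WT replicate 1 (0.0668) or 2 (0.0677), with library size alone (0.0646), with sex as a covariate (0.0642) and with the GC and length offset (0.0507), while its log2 change stayed between 0.43 and 0.48. Sterol synthesis genes rose (median 0.19, 17 of 22 above 0, 0 called, camera adjusted p = 0.00179; adjusted p = 0.402 with an estimated correlation). Glucocorticoid-induced genes fell (median -0.21, 3 of 16 above 0, 0 called in edgeR, camera adjusted p = 0.00196; adjusted p = 0.402 with an estimated correlation), with Tsc22d3 at -1.18 ± 0.30 and Fkbp5 at -0.50 ± 0.17. Tsc22d3 passed in DESeq2 (0.0462) and in edgeR without young WT replicate 1 (-1.52, adjusted p = 0.00162). The m6A readers and erasers were called lower (median -0.03, camera adjusted p = 0.000286; adjusted p = 0.402 with an estimated correlation), with Igf2bp3 as the only member called of 12. The list of m6A methyltransferase genes was not called (median -0.01, mean 0.01, test upward, 0 of 9 members called, camera adjusted p = 0.956).

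Markers of several other cell types were higher in old WT. All 13 B cell genes were above 0 (median 2.90, camera adjusted p = 7.21e-11; adjusted p = 0.402 with an estimated correlation). None passed over all genes in edgeR and 12 were higher adjusted over the list alone, among them the B cell receptor gene Cd79a (2.90 ± 0.84) and Cd22 (4.72 ± 1.38). DESeq2 called Cd22 (0.00386), Cd79a (0.0342) and Ighd (0.0448), and edgeR called Cd22 with the replicate number as a block (0.0453). Myeloid genes (median 1.75, 11 of 11 above 0, camera adjusted p = 0.000462; adjusted p = 0.457 with an estimated correlation), mature single-positive thymocyte genes (median 1.02, 15 of 16 above 0, 0.00123; adjusted p = 0.527 with an estimated correlation) and NK, NKT and gamma-delta genes (median 1.01, 9 of 9 above 0, 0.00816; adjusted p = 0.457 with an estimated correlation) rose as groups, with no member called in edgeR. The dendritic (0.134), thymic epithelium (0.73) and erythroid (0.956) lists were not called, though the dendritic list passed upward with the replicate number as a block (0.0201) and without old WT replicate 1 (0.0297) or 4 (0.0125). Old WT replicate 3 held the highest level of several, as in Igkc and Lyz2, both chosen after their values were seen, and Cd74: Igkc was 379 CPM there beside 12.4 to 80.8 in the other old WT libraries, Cd74 315 beside 18.3 to 49.4, and Lyz2 62.8 beside 6.16 to 7.83. Without old WT replicate 3 the mature thymocyte (0.0978) and NK, NKT and gamma-delta (0.254) calls were lost, while the B cell (4.77e-10), interferon (4.32e-06), positive selection (9.42e-05) and histone (2.22e-20) calls remained, as did the myeloid call (0.035). The difference in mean log2 CPM fell without that library from 0.96 to 0.30 for myeloid genes, from 0.56 to 0.09 for mature thymocyte genes and from 0.70 to 0.25 for NK, NKT and gamma-delta genes. Old WT replicate 4 lay below each young WT library in mature thymocyte genes (3.28 beside 3.47 to 3.63) and NK, NKT and gamma-delta genes (1.96 beside 2.22 to 2.26), and without it the mature thymocyte difference was 0.85. Mitochondrially encoded genes were not called in all libraries (median 0.65, adjusted p = 0.158) and turned downward past the threshold without that library (0.0054). They passed upward without old WT replicate 4 (0.0349) and with the replicate number as a block (0.0371).

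**Figure D3:**
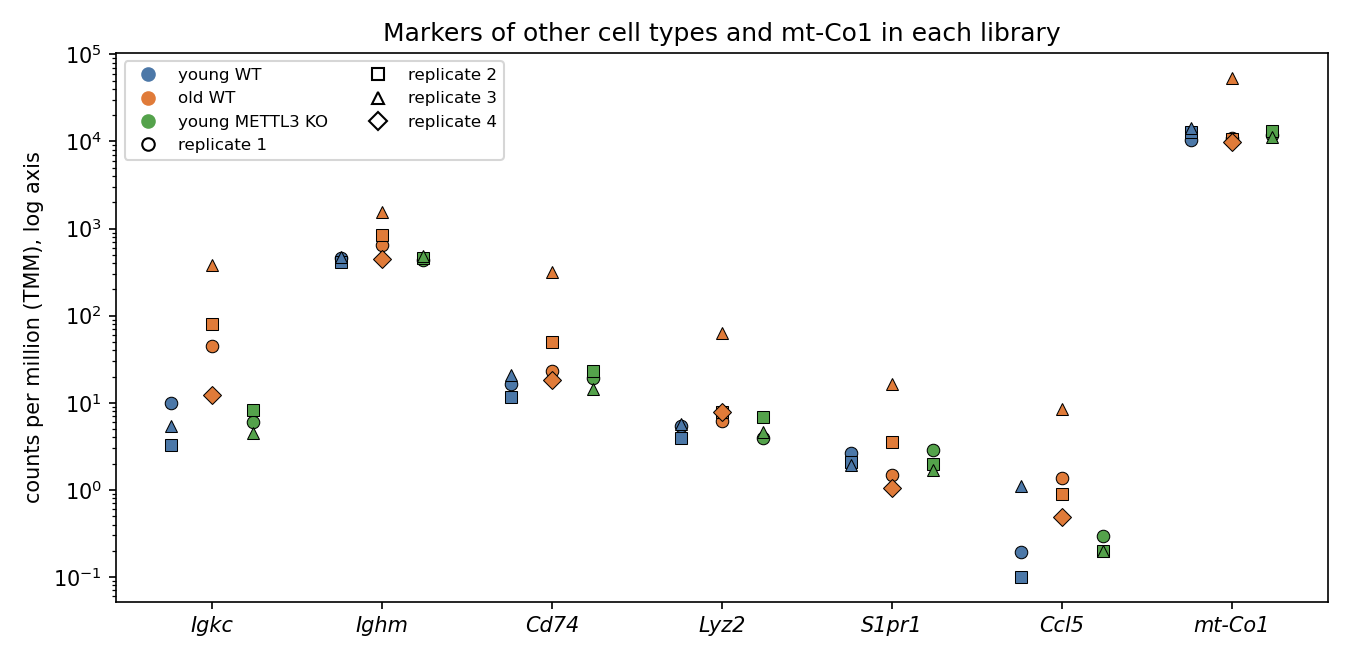
CPM, on a log axis, of 6 genes of B, antigen-presenting, myeloid, mature T and cytotoxic cells and of mt-Co1 in each library with an age. Old WT replicate 3 (orange triangle) is the highest library for each gene, with Cd74 at 315 CPM.

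The ferroptosis genes asked about by the study did not pass in edgeR with age. Tfrc, the transferrin receptor that brings iron into the cell, was 132 ± 11.3 CPM in old and 165 ± 4.08 in young WT (-0.32 ± 0.09, adjusted p = 0.23). Gpx4, which removes lipid peroxides, differed by -0.09 ± 0.11 and the cystine carrier Slc7a11 by -0.15 ± 0.25. Acsl4, which loads membranes with polyunsaturated lipid, differed by 0.13 ± 0.09, the ferritin chain Fth1 by 0.10 ± 0.12 and the ferritin receptor Ncoa4 by -0.25 ± 0.14. Ptgs2 was too low to be tested in any comparison. Genes that restrain ferroptosis (median 0.01, 0 of 22 called in edgeR, camera adjusted p = 0.492) and genes that promote it (median 0.04, mean 0.10, test downward, 0 of 23 called, 0.976) were not called. Adjusted over the list alone, 2 restraining genes were higher, Nfe2l2 (0.49 ± 0.10) and Scd1 (2.99 ± 0.82), both chosen for mention after their values were seen, and DESeq2 called both over all genes (0.00648 and 0.00596). The stage genes Rag1 (-0.25 ± 0.21), Cd4 (0.03 ± 0.11) and Cd8a (0.02 ± 0.09), Igf2bp2 (0.15 ± 0.30) and the cell-cycle inhibitor Cdkn1a (0.23 ± 0.32) did not pass.

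The young KO comparison asks what loss of METTL3 changes in young DP cells. No gene passed in edgeR between the 3 libraries labelled young KO and the 3 young WT libraries, and 88 of 14228 genes had an unadjusted p under 0.05 with a spread shared with old WT. A fit of these 2 groups alone also called 0, with 521 under 0.05. DESeq2 and limma-voom also called 0. With no filter on low counts, 1 gene passed, Tex11, a meiotic gene on the X chromosome named after its values were seen, with 30, 10 and 14 counts in young WT and 1, 0 and 0 in the libraries labelled KO (adjusted p = 0.00879). All 4 old WT libraries had 0 counts of Tex11 as well, so its loss is not particular to the libraries labelled KO. Ribosomal protein genes were higher as a group (median 0.10, 72 of 78 above 0, camera adjusted p = 1.21e-08; adjusted p = 0.992 with an estimated correlation), and so were interferon-stimulated genes (median 0.20, 29 of 33 above 0, 2.31e-06; adjusted p = 0.992 with an estimated correlation). Globin and other erythroid genes were lower (median -1.03, 0 of 4 above 0, 0.00247; adjusted p = 0.992 with an estimated correlation). No member of these lists passed, over all genes or adjusted over the list alone. In all, 8 lists were called, 4 in each direction. The other 5 were histone (0.0076) and oxidative phosphorylation genes (0.0432), higher, and early thymocyte (0.00564), fatty acid (0.0216) and mitosis genes (0.0491), lower, each with adjusted p = 0.992 with an estimated correlation. Without young WT replicate 1 there were 2 calls, and those 5 (0.5 to 0.723) and the ribosomal one (0.175) were lost. Without young KO replicate 1 there were 4 calls and without replicate 2 also 4, with losses among the same 5 at 0.0687 to 0.967. Oxidative phosphorylation (0.338) and histone genes (0.0609) were lost without young WT replicate 2, and fatty acid genes without young KO replicate 3 (0.0663), while DNA replication genes passed downward without young WT replicate 2 (0.0337) or young KO replicate 3 (0.0177). The oxidative phosphorylation call was also lost with sex as a covariate (0.0509) and with the GC and length offset (0.181), and the mitosis call with the offset (0.0721). The erythroid call was lost without young WT replicate 2 (0.0609) or young KO replicate 3 (0.279). The difference in mean log2 CPM of ribosomal protein genes (0.11) was 0.04 without young WT replicate 1 and 0.20 without replicate 3, that of interferon-stimulated genes (0.20) was 0.13 without young KO replicate 1, and that of erythroid genes (-1.21) was -0.52 without young KO replicate 3. The ferroptosis lists were not called (0.58 for genes that restrain it, 0.803 for genes that promote it).

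In the libraries without an age, the comparison asks the same of METTL3 in a separate set. Rag1, which cuts the receptor genes for rearrangement, fell from 5850 ± 738 CPM in WT to 1080 ± 121 in KO (5.43-fold lower, log2 change -2.44 ± 0.19, adjusted p = 4.11e-05, n = 3 each). Kcna3, a voltage-gated potassium channel of T cells, fell from 143 ± 11.7 to 8.34 ± 3.30 CPM (17.2-fold lower, -4.10 ± 0.26, adjusted p = 2.17e-05). Large falls were also seen in Vasn, which binds TGF-beta (-4.42 ± 0.54), Zfp871, a zinc finger gene (-4.0 ± 0.34), Klhl11 (-3.82 ± 0.30), Idi1 of sterol synthesis (-3.55 ± 0.37) and Adnp, a homeobox factor (-3.42 ± 0.45). The largest rises were in genes near silent in WT. Asic2, a neuronal ion channel, reached 19.9 ± 2.39 CPM from 0.344 ± 0.298 (5.81 ± 0.52), and the transcription factor Foxc1 21.8 ± 6.81 from 0.644 ± 0.286 (5.06 ± 0.39). Ncan, a brain proteoglycan (5.11 ± 0.58), the transcription factor Tfap2a (5.0 ± 0.41), Dnmt3l, a germline regulator of DNA methylation (4.88 ± 0.48), and Dnah2, an axonemal dynein (4.82 ± 0.54), also rose. Dnmt3l shares 67 bp with Aire and Idi1 323 bp with Gm48574 on the other strand.

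A total of 8864 of 16432 genes passed in edgeR, 4919 higher and 3945 lower in KO, and among genes of at least 5 CPM in WT, a set chosen after seeing the data, 1521 were higher and 3562 lower. Called genes were 55.5% higher, and 67.1% higher with an offset for GC content and transcript length, also chosen after seeing the data, which moved the median log2 change of all genes from 0.08 to 0.21. Across 9556 coding genes, which are not independent, fold changes in this KO ran with GC content (Spearman 0.46) and with transcript length (-0.38), against 0.29 and -0.03 for ageing and -0.03 and -0.15 for the libraries labelled young KO. Gene counts made up 27.28% to 29.46% of all counted entries in these KO libraries, beside 36.97% to 37.26% in their WT. Entries of low quality made up 1.19% to 1.51% in KO and 0.7% to 0.81% in WT. Both measures separate KO from WT, so the calls and lists of this set do not set genotype apart from library quality. How far library or RNA quality bears on them was not tested. The sexes read from Xist and Y-linked genes were 3 male in WT, and 2 female and 1 male in KO. With sex as a covariate, the genotype difference in this set therefore rests on KO replicate 3, the only male KO library. Calls gained or lost with that covariate in this set depend on this 1 library.

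Genes of the double-positive stage fell as a group in this KO, with 12 lower, 1 higher and 9 not called of 22 (median -0.61, camera adjusted p = 0.00223; adjusted p = 0.469 with an estimated correlation). Rag1, the E protein Tcf12 (-1.74 ± 0.18), Ets1 (-1.34 ± 0.17) and Ikzf1 (-1.17 ± 0.18), which encodes Ikaros, led them. Cd4 fell (-0.79 ± 0.17, adjusted p = 0.00269), while Cd8a did not pass (-0.21 ± 0.16, adjusted p = 0.29) except without KO replicate 3 (-0.35, adjusted p = 0.0347). V(D)J recombination and break repair genes fell, with 14 lower, 1 higher and 3 not called of 18 (median -0.64, camera adjusted p = 0.000525; adjusted p = 0.469 with an estimated correlation). The DNA damage kinase Atm (-2.37 ± 0.26) and the ligase Lig4 (-1.63 ± 0.19) were among them. DNA replication genes (14 lower, 1 higher, 11 not called; median -0.69, 0.00152; adjusted p = 0.473 with an estimated correlation) and mitosis genes (17 lower, 1 higher, 8 not called; median -0.73, 0.00018; adjusted p = 0.469 with an estimated correlation) fell too, as in Rrm1 (-1.51 ± 0.16), Mcm5 (-1.09 ± 0.15), Kif20a (-1.64 ± 0.18) and Ckap2l (-1.29 ± 0.16). Adjusted over each list alone, the counts were the same for these 4 lists, and each list passed with the GC and length offset too.

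The list of m6A methyltransferase genes, which holds Mettl3 itself, other subunits of its complex and Mettl16, fell. Of its 9 members, 8 were lower over all genes and adjusted over the list alone. Its median was -0.51 (camera adjusted p = 0.0251, or 0.469 with an estimated correlation). Rbm15b (-1.21 ± 0.16), Virma (-0.83 ± 0.16), Cbll1 (-0.80 ± 0.23) and Wtap (-0.50 ± 0.15), subunits that place the enzyme on RNA, had the smallest p. With the GC and length offset the list was not called (0.393), nor were Virma (-0.03, adjusted p = 0.849), Cbll1 (-0.24, 0.311) and Wtap (0.01, 0.969). Wtap was also lost with library size alone (0.0687), with the replicate number as a block (0.05) and without WT replicate 1 (0.0521). Sterol synthesis genes fell, with 11 lower, 3 higher and 9 not called of 23, the same adjusted over the list alone (median -0.57, camera adjusted p = 0.0251; adjusted p = 0.469 with an estimated correlation), with Idi1 among them. The sterol call was lost with sex as a covariate (0.0576). The list of cell-cycle inhibitors and other senescence genes was called lower (5 lower, 1 higher, 4 not called; 6 lower and 1 higher adjusted over the list alone; median -0.47, 0.0417; adjusted p = 0.469 with an estimated correlation). Rb1 (-1.66 ± 0.18) and Cdkn1b (-1.27 ± 0.20), which hold back the cell cycle, and Lmnb1 (-1.37 ± 0.17) of the nuclear lamina led it. The senescence call was lost without WT replicate 1 (0.122), 2 (0.1) or 3 (0.054) and without KO replicate 1 (0.104) or 3 (0.056), and with a filter of 1 CPM in 3 libraries (0.0654).

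**Figure D4:**
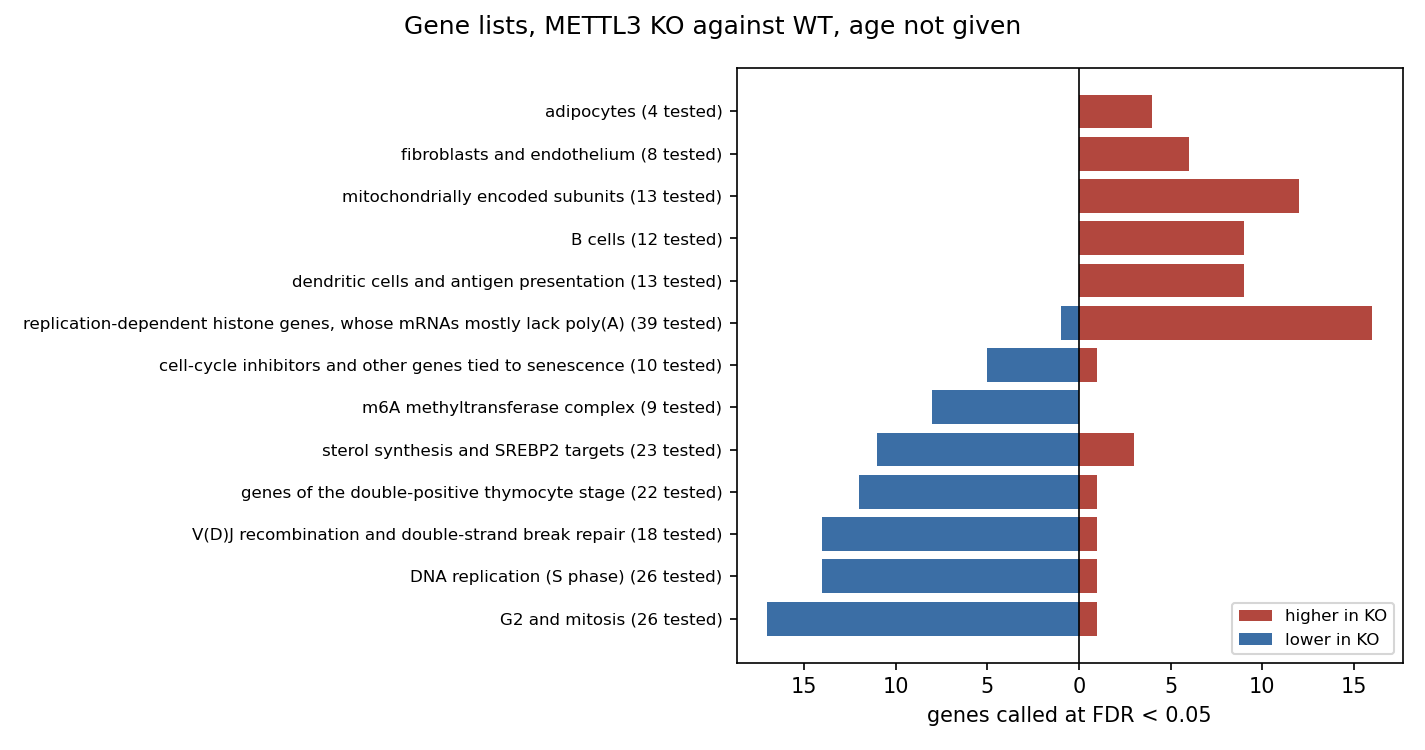
Number of genes called higher (red, right of 0) and lower (blue, left of 0) in KO libraries without an age, for the 13 gene lists called by camera with the preset correlation. Mitosis genes had 17 lower of 26 and histone genes 16 higher of 39.

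Other groups rose in the KO libraries without an age. Mitochondrially encoded genes were higher in 12 of 13 and in 13 adjusted over the list alone (median 1.71, camera adjusted p = 0.000821; adjusted p = 0.569 with an estimated correlation), with mt-Nd4 at 4480 CPM beside 1290 in WT (1.80 ± 0.28) and mt-Nd6 at 1.52 ± 0.25. Replication-dependent histone genes were higher in 16, lower in 1 and not called in 22 of 39, or 14 higher and 1 lower adjusted over the list alone (median 1.19, 0.0251; adjusted p = 0.683 with an estimated correlation), led by Hist1h1d (2.31 ± 0.42) and Hist1h2bj (1.93 ± 0.36). The histone call was lost with the GC and length offset (0.432) and without WT replicate 3 (0.065), KO replicate 1 (0.104) or KO replicate 3 (0.056). As noted for ageing, this is a quality list of mRNAs that mostly lack poly(A). Ribosomal protein genes were 21 higher and 57 not called, or 14 higher adjusted over the list alone. As a group they were not called (median 0.49, camera adjusted p = 0.0726) except without KO replicate 1 (0.0157) or 2 (0.00813). They also passed with sex as a covariate, a fit that rests on KO replicate 3. Their mean log2 CPM was 9.33 there, beside 8.391 and 8.385 in KO replicates 1 and 2. Ribosomal protein genes, histone genes, Fth1 and Gpx4 have near-identical copies or processed pseudogenes, so their counts are uncertain. Interferon-stimulated genes were 12 higher, 3 lower and 18 not called, the same adjusted over the list alone, and were not called as a group (0.211).

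Markers of several other cell types were also higher in KO. B cell genes were higher in 9 of 12 (median 1.57, camera adjusted p = 0.0118; adjusted p = 0.469 with an estimated correlation), as in Ebf1 (2.94 ± 0.41). Genes of dendritic cells and antigen presentation were higher in 9 of 13 (median 1.45, 0.0304; adjusted p = 0.569 with an estimated correlation), as in H2-Eb1 (1.66 ± 0.30) and Cd74 (51.9 ± 10.4 beside 20.3 ± 7.66 CPM, 1.35 ± 0.28; 0.89, adjusted p = 0.0558, with the offset). The dendritic call was lost without WT replicate 1 (0.0635) or 3 (0.054), without KO replicate 1 (0.104), with sex as a covariate (0.12) and with the GC and length offset (0.144). Fibroblast and endothelial genes were higher in 6 of 8 (median 3.05, 0.0284; adjusted p = 0.469 with an estimated correlation) and adipocyte genes in 4 of 4 (median 3.77, 0.0251; adjusted p = 0.469 with an estimated correlation), at low levels: Col1a1 was 4.15 CPM beside 0.647 and Cidec 3.90 beside 0.150. The fibroblast call was lost without WT replicate 1 (0.051), 2 (0.0613) or 3 (0.054), without KO replicate 2 (0.0548), with sex as a covariate (0.104) and with a filter of 1 CPM in 3 libraries (0.0604), and the adipocyte call without WT replicate 3 (0.0511), with sex as a covariate (0.0576) and with the offset (0.0527). Adjusted over each list alone, the counts of these 4 lists were the same. Among 10000 lists of genes matched on WT level, the dendritic list lay at percentile 99.54, B cell 94.97, adipocyte 77.53 and fibroblast 13.68. The fibroblast and adipocyte rises were therefore ordinary for genes of equal WT level. Myeloid genes (7 higher of 16, 0.0765), mature thymocyte genes (2 higher and 2 lower of 16, 0.771; median 0.12, mean 0.03, test downward), thymic epithelium genes (2 higher and 2 lower of 7, 0.777) and NK, NKT and gamma-delta genes (2 higher of 10, 0.721) were not called as groups.

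Genes of iron and lipid peroxidation moved in both directions in this KO. Ncoa4, which delivers ferritin for iron release, fell 6.53-fold from 81.6 to 12.5 CPM (-2.71 ± 0.26, adjusted p = 6.11e-05). Slc7a11 (-0.98 ± 0.18, adjusted p = 0.00102), Tfrc (-0.87 ± 0.20, adjusted p = 0.00326) and Acsl4 (-0.68 ± 0.19, adjusted p = 0.0109) fell, and with the GC and length offset stood at -0.04, -0.18 and 0.06, none called. Gpx4 was 160 ± 60.1 CPM beside 115 ± 6.36 and did not pass (0.47 ± 0.22, adjusted p = 0.0954). It passed with library size alone (0.0429) and without KO replicate 2 (0.04). With sex as a covariate it also passed, in a fit that rests on KO replicate 3. Gpx4 was 228.5 CPM there, beside 132 and 118.1 in KO replicates 1 and 2. Fth1 did not pass (-0.33 ± 0.25, adjusted p = 0.287) except without KO replicate 3 (-0.83, adjusted p = 0.00041). Cdkn1a did not pass (0.43 ± 0.46, adjusted p = 0.443), and the m6A reader Igf2bp2 rose (1.31 ± 0.31, adjusted p = 0.00402). Genes that restrain ferroptosis were 1 higher, 4 lower and 18 not called of 23, or 1 and 3 adjusted over the list alone (median -0.10, mean 0.21, test downward, 0.52), with the desaturase Scd2 at -1.68 ± 0.15, the heat shock protein Hspb1 at 6.38 ± 0.65 and the thioredoxin reductase Txnrd1 at -1.01 ± 0.16. Genes that promote it were 3 higher, 8 lower and 16 not called of 27, the same adjusted over the list alone (median -0.06, mean 0.16, test downward, 0.441), with the oxidases Alox12 (3.13 ± 0.49) and Nox1 (2.79 ± 0.48) higher and Ireb2, an iron sensor, lower (-0.91 ± 0.18; -0.08 and not called with the offset). Iron handling genes were 2 higher, 8 lower and 12 not called of 22, the same adjusted over the list alone, and the list was not called (median -0.27, 0.18) except without KO replicate 3 (0.0488).

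The differences between KO-labelled and WT libraries were compared directly between the 2 sets. The effect of the KO label differed in 6104 of 16557 genes in edgeR's test of the interaction, 3175 higher and 2929 lower in the set without an age. The balance moved with 1 library left out, to 1706 to 1905 higher and 3502 to 3659 lower without any 1 of the 6 young libraries, and to 2412 to 2883 higher and 3847 to 4466 lower without any 1 of the 3 KO libraries without an age. Mettl3 itself did not pass (-0.41 ± 0.19, adjusted p = 0.106). Among genes near silent in young libraries the fitted differences rest on few counts. Age and KO changes were set side by side across genes, which are not independent replicates, in 3 such relations and with no p-value. Fold changes of the 2 sets had a Pearson r of 0.001 and a Spearman rho of 0.039 over 12964 genes, with r from -0.016 to 0.024 when 1 library was left out. Ageing and the KO without an age gave r = 0.299 and rho = 0.32 over 12964 genes and share no library. Both ran with GC content (Spearman 0.29 for ageing and 0.46 for this KO). The correlation was not taken with the GC and length offset, so it is not set apart from a shared trend. Of the genes called in both, 9 were higher in both (2.95 if the lists were independent), 4 lower in both (4.51) and 3 opposite. The correlation was 0.139 without old WT replicate 3 and 0.204 without old WT replicate 1. Ageing and the libraries labelled young KO gave r = 0.227 and rho = 0.208 over 14228 genes, with a covariance of 0.0258. Both use the same young WT libraries. Against those libraries, 20 simulated unchanged groups gave r = 0.533 and a covariance of 0.0616, a difference in covariance of -0.0358. The simulation gave every library the spread estimated over all 10 libraries with an age. Old WT libraries differed more from each other (chi-square of counts per degree of freedom 13.51 to 72.55) than young WT libraries (3.2 to 10.2). The simulated values may therefore be too high, and no conclusion is drawn from the difference. That correlation was 0.432 without young WT replicate 1 and 0.006 among genes of 10 CPM or more.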

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

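The tests for cells that kept Mettl3, for other cells in old WT replicate 3, for evenly spread genomic DNA and for the X chromosome ratio were chosen after the results they concern were seen. Dixon's test of a single sample far from the rest was run in old WT, with 4 libraries, and groups of 3 were not tested. Of 67 values, 6 had such a library, and chance marks about 1 in 20 groups. Replicate 4 stood apart in Cd4 (1532 CPM beside 1221 to 1267, a gap of 0.852 of the range). Replicate 3 stood apart in the mean log2 CPM of mitochondrially encoded genes (10.46 beside 8.0 to 8.28, gap 0.887), of myeloid genes (4.36 beside 1.55 to 1.94, gap 0.861) and of BCL2-family survival genes (6.22 beside 5.92 to 5.95, gap 0.897). It also had fewer counts outside genes (47.5% beside 50.3% to 50.8%, gap 0.857) and more reads not uniquely aligned (9.18% beside 4.46% to 5.1%, gap 0.864).

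Other cells in old WT replicate 3 may account for this. Its B cell, myeloid, dendritic and NK lists stood at a median of at least 4.66 times the other old WT libraries (5.02, 9, 10.4 and 4.66), with Igkc, Cd74 and Lyz2 the abundant transcripts, and mitochondrial genes took 8.9% of gene counts beside 1.83% to 2.09%. The DP sort should remove such cells, and thymocytes themselves express part of the mature T cell genes. RNA quality was read as a trend with transcript length, predicted to be most negative in replicate 3. The Spearman correlation was -0.317 there, beside -0.489, 0.401 and 0.442 in old WT replicates 1, 2 and 4. The prediction was not met, but replicate 3 does have a negative trend, so RNA quality stays open. A difference between the animals themselves stays open and was not tested.

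Over all genes, the difference between KO-labelled and WT libraries was not the same in the young set and the set without an age in 6104 genes by the interaction test in edgeR. Of 48 named genes tested, 35 differed, 15 with a higher and 20 with a lower log2 change in the set without an age. Most of the 48 were named for a large change or a small p in the set without an age, while the young set has 0 calls, so this share follows largely from how they were chosen. The difference (set without an age minus young set) was below 0 in Vasn (-4.46), Kcna3 (-3.94), Zfp871 (-3.83), Klhl11 (-3.69), Idi1 (-3.36), Adnp (-3.25), Ncoa4 (-2.50), Rag1 (-2.20), Atm (-2.10), Tcf12 (-1.50), Scd2 (-1.41), Kif20a (-1.40), Rrm1 (-1.29), Ckap2l (-1.05), Rbm15b (-0.97), Mcm5 (-0.87), Cd4 (-0.70), Virma (-0.70), Slc7a11 (-0.62) and Tfrc (-0.60). It was above 0 in Col1a1 (3.07), Ebf1 (2.96), Hist1h1d (2.31), mt-Nd6 (2.10), mt-Nd4 (2.05), Hist1h2bj (1.68), H2-Eb1 (1.65), Rpl21 (1.46), Cd74 (1.31) and Rpl41 (1.19). Hspb1 (9.40), Foxc1 (7.70), Dnmt3l (7.05), Dnah2 (7.01) and Ncan (6.08) also differed, with 0 to 9 counts per young group, so their fitted differences are no bounds. Of 100 splits of the 12 libraries within their sets, 1, the real one, gave as many genes (highest other 6055), but this rests on the set without an age: the 9 others that kept its real split gave 5857 to 6055, and the 90 others gave 0. The count is therefore almost the same however the young libraries are grouped.

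No gene was called between the libraries labelled young KO and young WT in edgeR, with 88 at an unadjusted p under 0.05 and 0 in DESeq2 and limma-voom. Too little depth is argued against for changes of 2-fold or more in genes of at least 5 CPM. Of simulated 2-fold changes in such genes, 91% were recovered at this size, with 200 genes changed. Smaller changes stay open, with 40.3% recovered at 1.5-fold, as do genes of lower level and a case of few changed genes. Cells that kept Mettl3 in the libraries labelled KO are consistent with the values: the 95% interval of the Mettl3 log2 change reached down to -0.2, above the -0.58 ± 0.18 of the other set, which stood at -0.49 (adjusted p = 0.0398) with the GC and length offset, although the direct test of the difference in edgeR did not pass (-0.41 ± 0.19, adjusted p = 0.106). A deletion that leaves the gene count unchanged stays open, as do Tox4 reads within the young Mettl3 counts. A biological difference between sets stays open too, since the age of the other set is not given. The 10 splits of these 6 libraries are too few for a share under 0.05 (real value 0, highest other 1, and 10 of 10 gave as many).

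Counts outside genes were a signal not used in the comparisons: 47.9 ± 7.5 per 100 gene counts in the KO libraries without an age, beside 20.1 ± 0.6 in their WT. Coding genes near silent in young WT (10815) took 0.836% to 0.964% of gene counts in the same libraries and 0.172% to 0.205% in their WT, a ratio of means of 4.69, with 5178 to 5426 of them detected per KO library. The GC and length offset left a median log2 change of 3.15 (interquartile range 1.89 to 3.94) beside 2.90 before, over 1481 of them that averaged at least 1 CPM in these 6 libraries. That filter picks genes high in KO, so these medians do not measure the size of the rise. The offset was learned from genes of higher level, and it did not lower the median. Whether a trend among near-silent genes themselves adds to the rise stays open. Cells of other types are consistent with part of it: the dendritic list lay at percentile 99.54 of 10000 lists matched on WT level (B cell 94.97, adipocyte 77.53, myeloid 49.83, fibroblast 13.68), with Cst3 at 67.7 CPM beside 66.9 and Cd74 at 51.9 beside 20.3, although the DP sort should remove such cells. Genomic DNA cannot be told apart: the density at near-silent genes, taken genome-wide, was 1.26 to 1.5 times the counts outside genes, a bound that fails because those genes are not all silent, as the ratio was 0.54 to 0.649 at 6444 genes without counts in young WT. An even spread is argued against, since at most 30.3% of those genes had a count where 84.1% to 86.5% would. The male to female X ratio was 0.532 (0.4 to 0.699 over 1000 resamples of genes). That interval does not cover the spread between libraries, and the ratio rests on 1 male library. Loss of METTL3 itself, as a biological source, was not tested apart from these or from library quality, which also differed between KO and WT.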

How the results depend on the processing

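The block, the left-out libraries and the other settings were planned, while sex as a covariate, the GC and length offset and the genes of 5 CPM or more in WT were chosen after the data were seen; where a call changed, the cause was not tested unless stated. For ageing, 36 genes became 85 with no filter (59 higher, 26 lower), where 29923 genes were tested, 153 in DESeq2, 61 with the replicate number as a block (40 higher, 21 lower), 11 with the old and young WT groups alone, and 23 with a 2-fold threshold added, which can only remove calls. Leaving out 1 library gave 8 to 59. Only old WT has a replicate 4, so in the age comparison the block in effect also leaves that library out. Size factors of DESeq2 (36), library size alone (36), 1 CPM in 3 libraries (35), limma-voom (35), sex (32) and the offset (45) stayed within 1.5 times. The 19 list calls became 0 with an estimated correlation and 1 with fry (p53 targets, adjusted p = 0.039). The mitosis list turned upward with the block (0.221) and ranged from 0.000195 to 0.208 over the left-out libraries, turning upward without old WT replicate 4. Mitochondrially encoded genes ranged from 0.0054, turned downward, to 0.543.

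For young KO, 0 genes stayed 0 in each setting but no filter (1), and the 8 list calls became 0 with an estimated correlation, 0 with fry and 2 to 8 with 1 library left out. For KO without an age, 8864 genes became 5809 with a 2-fold threshold and 5083 among genes of 5 CPM or more in WT, and 7642 to 10731 in the other settings. Library size alone and the offset moved the median log2 change of all genes to 0.18 and 0.21. Its 13 list calls became 0 with an estimated correlation, 24 with fry and 8 to 16 with 1 library left out. Mettl3 ranged from -0.8 to -0.53 over the left-out libraries and was -0.48, not called, with library size alone. With the offset, Acsl4 (0.06), Wtap (0.01), Cflar (0.1), Edem1 (0.04) and Ly75 (0.09) turned upward and were not called. The interaction count ranged from 4543 with the block to 7349 without KO replicate 2 of the set without an age.

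Fold change correlations with 1 library left out ranged from 0.147 to 0.432 (ageing and the libraries labelled young KO), 0.139 to 0.37 (ageing and KO without an age) and -0.016 to 0.024 (both KO-labelled sets). Among genes of 10 CPM or more they were 0.006 for the first and 0.056 for the last, whose Spearman rho was 0.039. Replicate numbers do not pair the samples: libraries with the same number correlated at -0.488 to 0.281 in their deviations from group means. Among libraries with an age, pairs from different groups ran with the inferred sex. Pairs of like sex correlated at 0.12 to 0.639 and pairs of unlike sex at -0.488 to -0.039. Young WT replicate 1 was the only female library of its group, so leaving it out also changes the sexes compared. In simulations of the KO without an age, 9% of 1.5-fold changes were recovered, against 40.3% for young KO and 50.7% for ageing; its libraries are deeper, while its spread (coefficient of biological variation 0.241 against 0.166) is larger and its residual degrees of freedom (4 against 7) are fewer.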

Other observations

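Sex as a covariate, the GC and length offset and the left-out differences in mean log2 CPM were added after the data were seen. The other tests here were planned before their results were seen. The gene groups not described in the comparisons were chosen for mention afterwards. In old WT, 4 further lists were called higher by camera: targets of p53 (median log2 change 0.15, 2 of 21 higher adjusted over the list alone, adjusted p = 0.0378; adjusted p = 0.402 with an estimated correlation), SOCS and JAK-STAT genes (0.11, 2 of 18, 0.036; adjusted p = 0.402 with an estimated correlation), fatty acid genes (0.11, 1 of 24, 0.0191; adjusted p = 0.457 with an estimated correlation) and immediate-early and heat-shock genes that handling can raise (0.15, 5 higher and 1 lower of 16, 0.036; adjusted p = 0.434 with an estimated correlation). The p53 call was lost without young WT replicate 1 (0.113) or 2 (0.0946) and old WT replicate 1 (0.0622), 2 (0.128) or 4 (0.0638), with the replicate number as a block (0.0925) and with sex as a covariate (0.0519). The SOCS call was lost without young WT replicate 2 (0.0679) or 3 (0.098) and old WT replicate 2 (0.0953) or 4 (0.114), with the block (0.114) and with the GC and length offset (0.124), and the handling call without young WT replicate 1 (0.113) or 2 (0.0949) and old WT replicate 1 (0.178) or 2 (0.0722) and with the offset (0.0743). The fatty acid call was lost without young WT replicate 2 or 3 and old WT replicate 2 or 3 (0.0679 to 0.134) and with the offset (0.0524). The difference in mean log2 CPM of p53 targets (0.10) was 0.06 without old WT replicate 2, and that of fatty acid genes (0.20) was 0.11 without old WT replicate 3.

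In KO libraries without an age, genes of earlier thymocytes were 5 higher and 2 lower of 18 (camera adjusted p = 0.297). The stem cell factor receptor Kit (1.83), Hhex (3.96), Meis1 (2.87) and Spi1 (2.13) were higher. With sex as a covariate, a fit that rests on KO replicate 3, Spi1 stood at 1.46 and was not called. The m6A readers and erasers were 3 higher and 8 lower of 13 (0.171), with Igf2bp1 (4.02) higher and the erasers Alkbh5 (-1.06) and Fto (-0.89) lower. Genes raised on positive selection were 2 higher and 8 lower of 23 (0.0671), and passed downward without WT replicate 1 or 2 or any of the 3 KO replicates (0.0102 to 0.0466). T cell receptor genes were 5 higher and 5 lower of 21 (0.777; median 0.24, mean 0.01, test downward), with Lat (1.03) and Lck (0.75) higher and Rasgrp1 (-1.34) and Cd28 (-1.51) lower. With all libraries, camera called 0 of these 4 lists, and fry called the earlier thymocyte (0.0458), reader and eraser (0.0237) and positive selection lists (0.0438).

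For old against young WT, 1 of 35 splits of the 7 libraries, the real split, gave as many genes (36, highest other 8), a share under 0.05. A split that mixes the ages adds any age difference to the spread within groups, which lowers its count. With 1 young WT library left out, the real grouping itself gave 8, 10 or 13 genes. The splits therefore do not exclude chance. For KO against WT without an age, the 10 splits are too few for a share under 0.05 (real value 8864, highest other 0).

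Igf2bp3 and Plag1 are predicted targets of let-7 RNAs and fell with age (-3.14 and -1.23), so other targets were tested. The camera p of the 21 others tested was 0.606, with a median of -0.04 and 12 below 0. A fall of let-7 targets as a group was not seen, though a small change is not excluded. Exon density, which may bear on m6A placement, had a partial Spearman correlation across genes of 0.066 with fold changes in the KO without an age, given GC content and transcript length, and -0.172 in the libraries labelled young KO. Neither bound set for the test was met, so it leaves the question open. Single-exon genes that lie opposite the exons of a gene of 20 CPM or more had a median density of 0.979 of that gene in libraries with an age (96 genes) and 0 in the others (92 genes), so the sets differ in the strandedness of the libraries or of the counting.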
